A study of Homo sapiens with 32 samples.

How the data were processed

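RNA was sequenced from HCET cells, a human corneal epithelial cell line, that carry a doxycycline-inducible short hairpin RNA (shRNA) against PNN. Per the labels, total RNA was taken from untreated cells and from cells given doxycycline at 1 µg/ml for 48 to 72 h, and each of 4 control and 4 doxycycline libraries was sequenced in 4 lanes, which makes 32 samples. The labels call the lanes technical replicates. They do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between libraries, which may be technical. Per the submitters' processing notes, Bowtie 0.12.9 and BWA 0.7.2 were used with the builds hg19 and GRCh37; the role of each aligner, the counting rule, the use of strand and the statistical test are not given in the sources used here.

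The values analysed are the authors' own comparison table, which holds no value per library. Per the file headers, 1 set of columns gives the mean over all libraries, the control mean and the doxycycline mean of each of 36274 RefSeq records. These means are a signal, normalised reads that the authors divided by a size factor per library. The authors' deposited ratio column, a fold change, equalled the doxycycline mean divided by the control mean within 1e-06 in all 36274 records, and the deposited log2 column was the log2 of that ratio in all of them. The authors' deposited p-value and adjusted p-value columns were used as they stand. The adjusted p-values imply a correction over about 46448 records, more than are listed, and no listed record had a mean of 0 in either group. The header names C1, C2 and C3 for control and D1, D2 and D3 for doxycycline, whereas the labels hold 4 libraries per group.

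A record is 1 RefSeq sequence. Transcript records (curated or predicted mRNAs and non-coding RNAs) made up 71.2% of the list, and the others were genomic: RefSeqGene regions with their introns and flanks, or genomic scaffolds. The file pairs 34405 records with 20837 gene symbols. For 813 of 7794 gene-region records the symbol is that of another gene than the description names, as regions overlap; the symbol column was used for counts over genes, and records of this kind that are named below go by their description. Row descriptions mention GRCh38 loci while the notes name hg19 and GRCh37, so no coordinates are given. How reads with several equal matches were counted is not given in the sources used here. The 2 listed HSPA8 transcript records had control means of 1.79 and 0.381 normalised reads in the authors' deposited table. Levels of genes with close paralogs or pseudogenes, among them HSPA8P5, HMGB3P32 and the ribosomal proteins, are therefore uncertain, as are antisense and overlapping genes.

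A record was called changed where the authors' adjusted p was under 0.05, and a gene where at least 1 of its transcript or gene-region records was called. Designs fixed before the data were examined foresaw limma or a count test on values per library and, where a table held none, a description of the authors' own values, which is what is given here. Camera, planned for the gene lists, needs values per library, so members of 32 lists fixed beforehand were counted in the deposited table. For the 30 lists with at least 3 members among the 12368 genes with 20 or more normalised reads over both groups, called members were compared with the 135 called genes of that pool by a one-sided Fisher's exact test, adjusted by Benjamini-Hochberg over the lists. That test takes genes as independent and does not measure the spread between libraries. Its p-values may therefore be too small where genes of a list move together. The median log2 fold change of a list, from reads summed over the records of a gene, was placed among 10000 random lists of the same size matched on level and on having a gene-region record; that percentile describes these libraries and is not a p-value. Adjusted p "over the list alone" is Benjamini-Hochberg over the members' Simes p per gene; counts at an unadjusted p are of genes with at least 1 record under it.

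Reads per library were then re-derived, a step chosen after seeing the data. Each group mean is a sum of whole reads in 3 libraries, each multiplied by a fixed step, the inverse of 3 times that library's size factor. The steps gave size factors of 1.03, 0.958 and 0.874 for control libraries a, b and c and 1.21, 1.04 and 1.01 for doxycycline libraries a, b and c. The letters run from the largest to the smallest size factor within each group and match no library number of the labels. For means up to 400, 97.6% of control values and 98.0% of doxycycline values had a single solution in whole reads, and 75 and 15 had none. Both groups were solved for 30884 records, 85.1% of the list, including 69 of 155 called records. On simulated reads 91.1% of values had a single solution, and 100% of those were right. The total depth of each library is unknown, because records with higher means were not solved; the solved records held between 669106 and 917843 reads per library.

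The 11244 solved records with a mean of at least 10 were tested with limma 3.58.1 (R 4.3.3; eBayes with trend and robust) on log2(reads / size factor + 1), so a fold change on that scale understates the change of low records. In simulated reads for these 11244 records with 200 changed, limma called 6%, 74%, 88% and 92% of records changed 1.5-fold, 2-fold, 3-fold and 4-fold, and 2.26% of its calls were false. Each record was drawn on its own at a fixed dispersion of 0.02, with no structure shared within libraries. The real libraries had such a structure, so these rates may not hold for the real reads. Camera and fry were run on the same log2 values, averaged over the solved records of each of 8365 genes, for the 28 lists with at least 3 of them. Unequal change among the transcript records of a gene was tested with limma's diffSplice in 1393 genes with at least 2 such records. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.

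Genes named in the text follow a rule fixed beforehand: PNN; the 12 genes with the largest rise and the 12 with the largest fall in deposited fold change among those past the adjusted p of 0.05; up to 4 members with the smallest adjusted p of each list, with members needed to show mixed directions; and the 10 genes with the smallest p for unequal change. As the table holds no values per library, the rule's condition on no overlap between libraries was not applied. Others are said to be chosen after their values were seen. Alternatives were other thresholds, filters, pseudocounts and scalings, transcript records alone, and leaving out each library. Mitochondrially encoded genes and mitochondrial ribosomal proteins, the remaining 2 lists, were not analysed here. A further list and some genes that the rule names are not reported here.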

Results

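The expression of 36274 RefSeq records was compared between untreated HCET human corneal epithelial cells and HCET cells in which doxycycline had induced an shRNA against PNN. PNN encodes pinin, a protein of desmosomes and of nuclear speckles that binds the exon junction complex. The series states 2 questions, which genes change in expression and which change in splicing. Values below are normalised read means from the authors' deposited table, in which 3 libraries per group were averaged, unless they are said to be reads re-derived per library; the labels list 4 libraries per group. The control means summed to 12811221 normalised reads and the doxycycline means to 13223186. The deposited means carry no error, and no cells given doxycycline without the shRNA were among the samples, so the drug and the knockdown change together in every comparison.

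PNN mRNA (NM_002687.3) fell from 7825 normalised reads in control to 3558 after doxycycline, a fold of 0.455 (log2 fold change of -1.14, adjusted p = 3.46e-05 in the authors' deposited table). No other PNN record was listed, and its mean is too high for reads per library to be re-derived.

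An adjusted p of 0.05 in the authors' deposited table was passed by 155 records, of which 104 were higher and 51 lower after doxycycline. Apart from 14 scaffold records they belong to 137 genes, 93 that rose and 44 that fell, and no gene had called records in both directions. All 155 changed by at least 0.77 on the log2 scale, and 118 by 1 or more. At an unadjusted p under 0.05 there were 2163 records. The record classes did not share a midpoint. Among records with a mean over 50, the 5760 transcript records had a median log2 fold change of 0.16 and 67.1% of them were higher, whereas the 3831 gene-region and scaffold records had a median of -0.19 and 22.6% were higher. Genomic records held 38.4% of control reads and 32.9% of doxycycline reads. Relative to its class median PNN changed by -1.29. Each of the 155 called records kept its direction, which was certain beforehand because all changed by more than either class median.

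**Figure D1:**
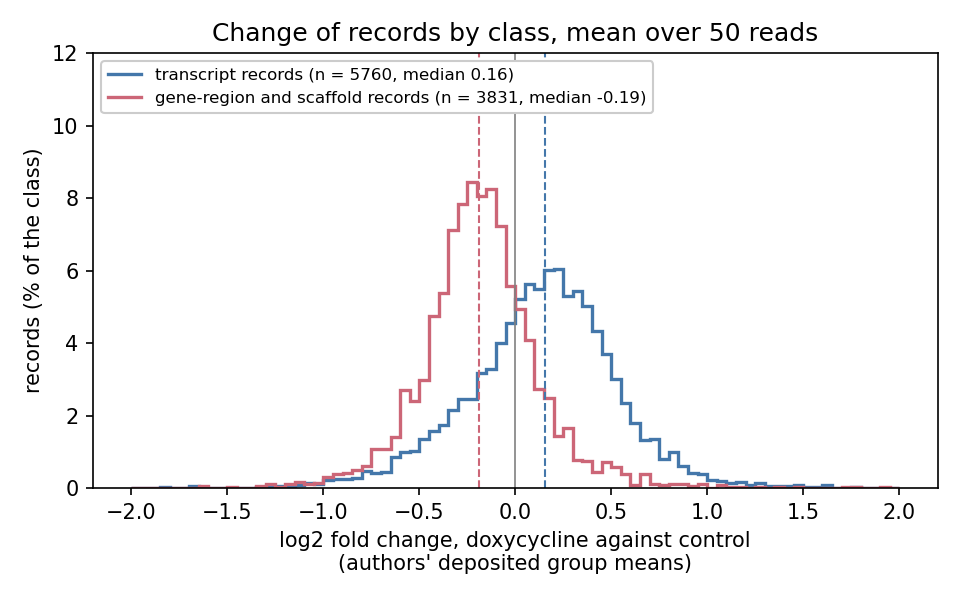
Distribution of the log2 fold change in the authors' deposited table (x axis, doxycycline against control, drawn from -2 to 2) for transcript records and for gene-region and scaffold records with a mean over 50, as a percentage of each class (y axis). Dashed lines mark the medians, 0.16 for 5760 transcript records and -0.19 for 3831 genomic records.

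The largest rises included genes of a protease, a protease inhibitor, a cytokine and a kinase, and several transcripts with few reads. By the authors' deposited table SERPINB2, a plasminogen activator inhibitor, rose 45.1-fold from a control mean of 0.696 to 31.4 reads (adjusted p = 0.000874). That control mean rests on 2 reads against 101, a ratio of 44.4 with an exact Clopper-Pearson 95% interval of 11.97 to 371. The interval covers counting error only and takes each read as an independent count. Among records read in only 1 control library, 2115, 2010, 467 and 538 had totals of 1, 2, 3 and 4 reads. Even totals were thus frequent, so reads may not be independent and the interval may be too narrow. TMPRSS11E, a transmembrane serine protease of squamous epithelium, rose 19.1-fold from 12.5 to 240.0 reads, and ALPK2, an atypical protein kinase, rose from 53.8 to 775 reads, 14.4-fold. IL1A, the alarmin interleukin 1 alpha, rose 9.79-fold (6.08 to 59.5 reads), PLA2G4E, a cytosolic phospholipase A2, 11.1-fold, NEFL, neurofilament light chain, 8.70-fold, and AGPAT9, a glycerolipid acyltransferase, 8.26-fold. The rest of the 12 largest rises were UNC5C, ZP4, NPAS2, TRIB1 and the pseudogene HMGB3P32, all with control means under 4 reads. For UNC5C (1 control read), NPAS2 and TRIB1 the called record is a predicted transcript variant, and the curated NPAS2 mRNA had 13.9 and 45.1 reads (adjusted p = 0.0708).

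The largest falls were in low to moderate transcripts. HSPA8P5, a pseudogene whose level is uncertain because it resembles HSPA8, went from 21.6 to 2.51 reads, ADARB2 from 24.4 to 3.83, the non-coding RNA LINC00601 from 28.6 to 4.65, and LYPD2 from 22.3 to 3.93. ABCA4, a retinoid transporter of photoreceptors, fell in its mRNA from 330.3 to 59.9 reads (log2 fold change of -2.46) and in its gene region from 843 to 191.9 reads (log2 fold change of -2.14), both in the authors' deposited table. IGFBP5, an insulin-like growth factor binding protein, fell 4.14 times, ZBTB8B 3.79 times, TNNC1, a troponin, 3.70 times, VGLL1, a cofactor of TEAD transcription factors, 3.60 times and INSL4, a placental relaxin family hormone, 3.53 times. FGD3, in a predicted non-coding variant, fell 4.06 times and STAU2-AS1, an antisense RNA for which strand was not given, 3.50 times.

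**Figure D2:**
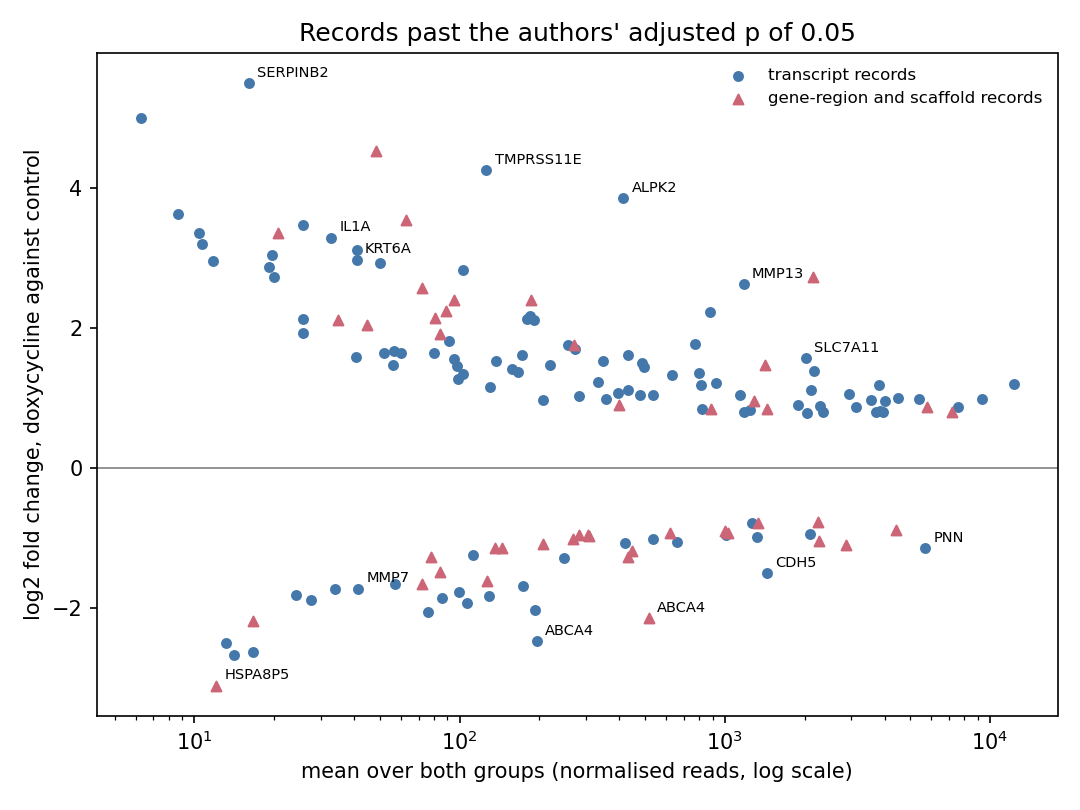
Log2 fold change (y axis) against the mean over both groups on a log scale (x axis, normalised reads) of the 155 records past an adjusted p of 0.05 in the authors' deposited table. Circles are transcript records and triangles are gene-region and scaffold records; PNN lies at a log2 fold change of -1.14.

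Reads per library could be re-derived for 69 of the 155 called records, and in all 69 each of the 3 doxycycline libraries lay beyond each of the 3 control libraries. Chance gives this in 10% of records, but these were selected by the authors' adjusted p on the same libraries, so it is no independent test. Of all 11244 records tested with limma, 17.3% had no overlap. IL1A had 4, 5 and 8 reads in the control libraries and 60, 95 and 38 in the doxycycline libraries, and SERPINB2 had 0, 2 and 0 against 27, 50 and 24. INSL4 had 248, 166 and 168 reads against 80, 58 and 50. With limma on the re-derived reads, 71 of 11244 records passed an adjusted p of 0.05, 48 higher and 23 lower, and 54 of the 67 records that the authors' deposited table calls among them were called in the same direction. At an unadjusted p under 0.05 limma had 1409 records. Its count was 333 without control library b and between 24 and 73 without each other library, and it was 0, with 1228 records at an unadjusted p under 0.05, without the trend and robust options of limma. In a principal component analysis of these reads the first component held 36.3% of the variance, and control library b (12.4) lay apart from control libraries a (-51.4) and c (-33.4), while doxycycline library a lay at -1.35 and b and c at 38.2 and 35.6.

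**Figure D3:**
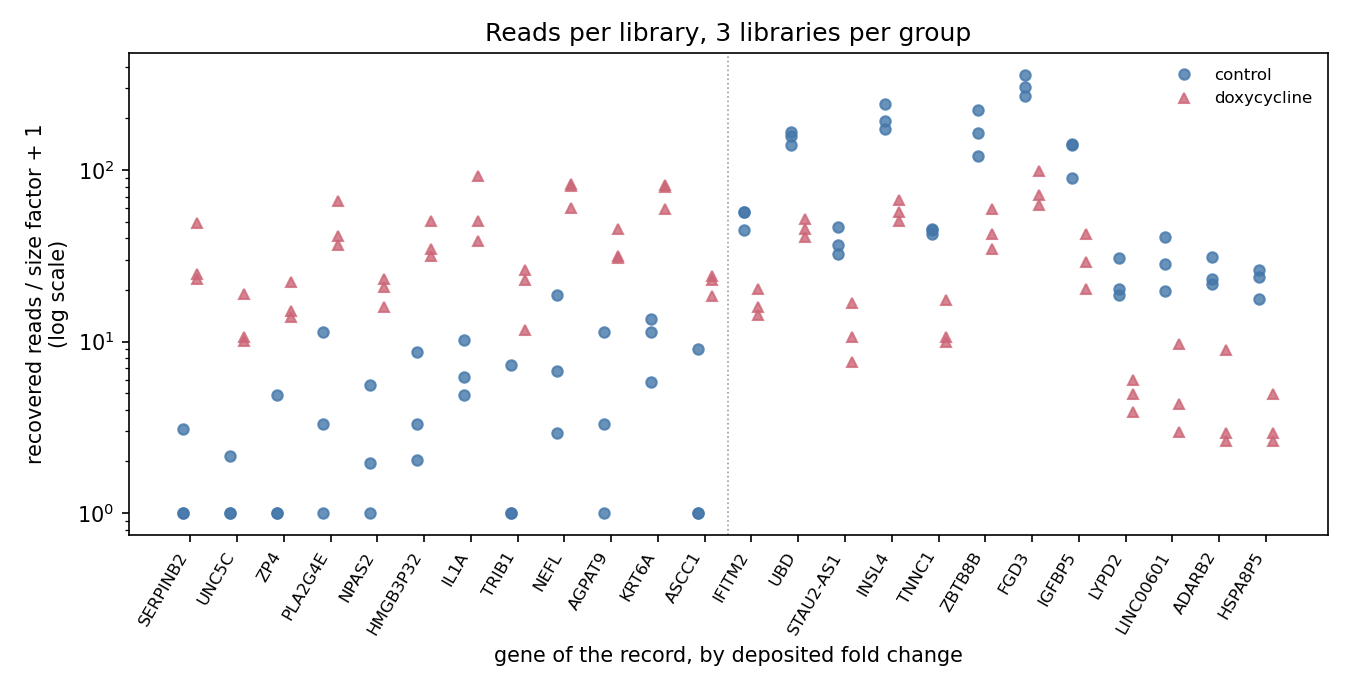
Reads re-derived per library, divided by the size factor, plus 1 (y axis, log scale), for 24 genes with solved called records, ordered by deposited fold change with the 12 largest rises on the left and the 12 largest falls on the right. Each symbol is 1 of 3 control (circles) or 3 doxycycline (triangles) libraries; in each gene shown the groups do not overlap.

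Of 29 listed epithelial-mesenchymal transition genes 4 rose and none fell, all of them secreted proteases that cut collagens and other matrix proteins: MMP13 rose from 328 to 2029 reads (6.18-fold), MMP1 from 310.3 to 1448 (4.67-fold), MMP10 from 66.6 to 301 (4.51-fold) and MMP9 from 48.3 to 142 (2.94-fold) in the authors' deposited table. This is more than expected from the 135 called genes in the pool (Fisher's exact test, adjusted p = 0.00183). The called records of MMP13, MMP1 and MMP10 were not solved, so limma's camera on re-derived reads ran without them. Over 16 genes of the list it gave no call (adjusted p = 0.148 with a correlation of 0.01 and adjusted p = 0.518 with an estimated correlation). It is therefore no check on those 3 rises. By the authors' deposited table, 5 members rose with p adjusted over the list alone, the fifth being TNC. The median over the list was 0.16 (percentile 99.92), and 0.34 (percentile 95.7) in transcript records alone. The transcription factors and mesenchymal proteins of that list did not pass; CDH2, N-cadherin, had 21.7 and 15.6 reads, and FN1, fibronectin, had 4589 and 3783 reads in its gene region. In the re-derived reads MMP9 had 53, 48 and 38 reads in control and 154, 163 and 143 after doxycycline (limma log2 fold change 1.53, SE 0.26, adjusted p = 0.00456), while its gene region had 70.04 and 49.2 in the authors' deposited table. MMP7, chosen after its values were seen and outside that list, fell from 63.6 to 19.3 reads.

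Of 20 listed NF-kB and inflammatory genes 5 rose and none fell (Fisher's exact test, adjusted p = 1.19e-05; camera on re-derived reads, adjusted p = 0.518 with an estimated correlation). Beside IL1A these are ligands of the neutrophil receptor CXCR2: CXCL3 rose 7.35-fold, CXCL1 4.38-fold, CXCL2 4.37-fold and CXCL8 3.41-fold (349 to 1190 reads) in the authors' deposited table. Adjusted over the list alone, 5 rose and 2 fell; CCL2, a monocyte chemokine, was among the latter with 10.3 and 1.32 reads, although its adjusted p over all records was 0.221. The median over the list's 15 genes in the pool was 0.20, at percentile 98.97 of random lists, and 1.13 (percentile 100) over the 14 with transcript records. Of the 30 lists tested 4 passed (these inflammatory genes, epithelial-mesenchymal transition, integrated stress response and cholesterol synthesis), and the remaining 26 had an adjusted p of 0.167 or more. On re-derived reads, which leave out abundant genes, limma's camera with a correlation of 0.01 called 5 of 28 lists, among them these inflammatory genes and the integrated stress response (each adjusted p = 0.00823), cholesterol synthesis (0.000376) and immediate early genes (0.0309), but not epithelial-mesenchymal transition. With an estimated correlation camera called 0 lists (smallest adjusted p = 0.518, 1 list at an unadjusted p under 0.05), and fry called 0 as moving on balance in 1 direction (smallest adjusted p = 0.0695, 6 lists at an unadjusted p under 0.05). In a test for change in either direction, which compares a list with no other genes, fry called 6 lists, these inflammatory genes (adjusted p = 0.00843), the integrated stress response (0.00194) and cholesterol synthesis (0.00266) among them.

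From 25 listed integrated stress response genes 3 rose: SLC7A11, the cystine transporter, from 1018 to 3032 reads (2.98-fold), PSAT1, of serine synthesis, from 213 to 651 (3.06-fold) and STC2, stanniocalcin 2, from 3002 to 6003 (2.00-fold), with none lower (Fisher's exact test, adjusted p = 0.0126). On re-derived reads the list was not called by camera with an estimated correlation (adjusted p = 0.518) or by fry in 1 direction (adjusted p = 0.137). Over the list alone 9 genes rose. The median was 0.42 over 22 genes, of which 19 were higher, and no random list had a higher median (percentile 100). TRIB3, a target of ATF4, had 24.4 and 65.2 reads (adjusted p = 0.0934 in the authors' deposited table). No unfolded protein response gene was called, against 5 of 19 with a record at an unadjusted p under 0.05. The median was 0.25 over 15 genes (percentile 97.0), and also 0.25 in transcript records alone, but there at percentile 73.4. With p adjusted over the list alone 2 genes rose: EDEM1 and HSPA5, encoding an endoplasmic reticulum degradation factor and chaperone, had log2 fold changes of 0.79 and 0.75 in the authors' deposited table.

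Immediate early genes had a median of 0.56, with 20 of 22 genes higher (percentile 100), and of 0.60 in transcript records alone. Only IER3 was called (2738 to 5331 reads, adjusted p = 0.0259; Fisher's exact test of the list, adjusted p = 0.609), but 6 genes rose with p adjusted over the list alone. Among these were ligands of the epidermal growth factor receptor: EREG had 4619 and 11363 reads, AREG 2774 and 8416, and HBEGF 248 and 1056, with adjusted p of 0.0613, 0.165 and 0.136 in the authors' deposited table. FOS itself had 42.9 and 42.8 reads. EGFR mRNA, chosen after its values were seen, rose 2.82-fold. The glycolysis and hypoxia list had 1 gene called, hexokinase HK2 (2.06-fold in a predicted transcript variant), with 2 higher over the list alone. Its median of 0.13 lay at percentile 92.5, and in transcript records alone it was 0.17, at percentile 62.7.

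Cholesterol synthesis genes were lower. The list's median was -0.64, with 20 of 21 genes lower and 9 lower with p adjusted over the list alone, and -0.57 in transcript records, each at percentile 0. Of 23 listed genes 3 fell past the adjusted p of 0.05 in the authors' deposited table and none rose (Fisher's exact test, adjusted p = 0.0126). Camera on re-derived reads did not call the list with an estimated correlation (adjusted p = 0.518), nor did fry in 1 direction (adjusted p = 0.0695). All of these calls are on gene-region records, whose class median is -0.19, and with transcript records alone none of 20 members was called. Among members that did not pass over all records, DHCR7, the last enzyme of the pathway, had 1317 and 792 reads in its gene region (adjusted p = 0.0900) and 208 and 138 in its mRNA, and SQLE, squalene epoxidase, had 8718 and 5936 in its mRNA (adjusted p = 0.48). EBP, a sterol isomerase, had 156 and 72.4 reads in its gene region (adjusted p = 0.0781) but 620 and 602 in its mRNA, all in the authors' deposited table.

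Interferon response genes had a median of -0.31 over 23 genes, 20 of them lower (percentile 0.01), yet none was called over all records or with p adjusted over the list alone. A record at an unadjusted p under 0.05 was found for 4 genes, 3 of them lower. IRF9, a subunit of the interferon-activated transcription factor, had 613 and 396 reads, and OASL, the fourth gene, had 77.7 and 121 reads. IFITM2 and UBD, both interferon-inducible, were chosen after their values were seen and fell 3.30 and 3.41 times in the authors' deposited table. Replication-dependent histone mRNAs had a median of -0.09 where matched random lists had 0.23 (percentile 0.01), with 0 of 23 called and 3 with a record at an unadjusted p under 0.05; HIST1H2BJ had 27193 and 16192 reads. The 50 ribosomal protein genes had a median of 0.01 where random lists had 0.18 (percentile 0.1); RPS16 rose from 745 to 1530 reads, 2 variants of RPS24 fell, and over the list alone 2 genes rose and 1 fell.

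**Figure D4:**
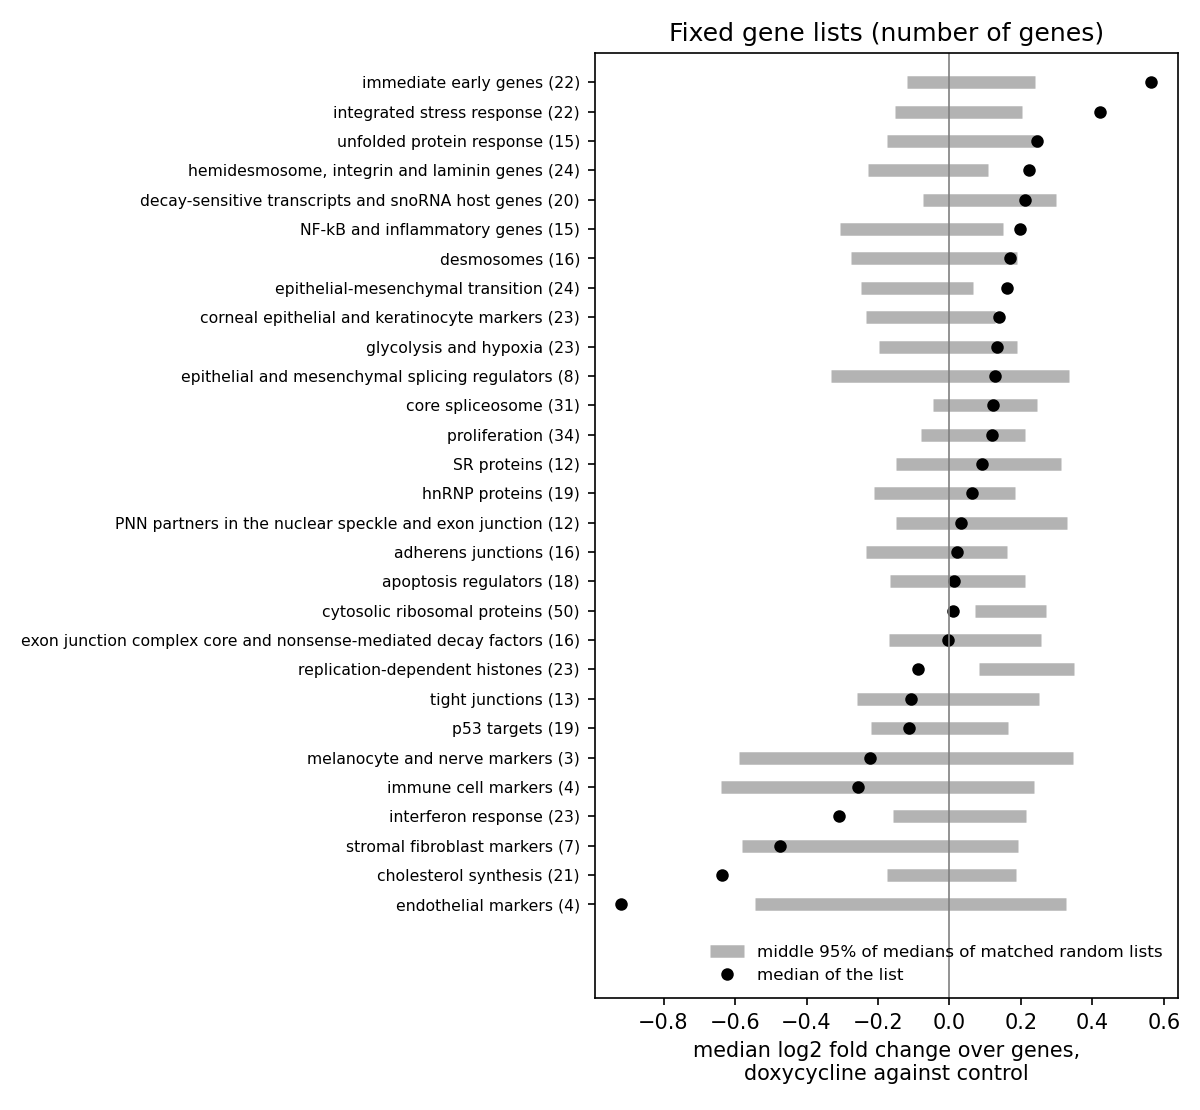
Median log2 fold change (x axis, doxycycline against control, reads summed per gene from the authors' deposited table) of fixed gene lists, with the number of genes in brackets. Grey bars span the middle 95% of the medians of 10000 matched random lists; the dots of immediate early genes (0.56) and cholesterol synthesis (-0.64) lie outside their bars.

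Over all genes in the pool 1.09% were called, so junction lists of this size would be expected to hold few calls or none. No desmosome gene was called, and 4 of 16 had a record at an unadjusted p under 0.05, 2 higher and 2 lower. The list's median was 0.17 (percentile 96.6), but 0.57 (percentile 99.85) over the 13 members with transcript records, some of them with few reads, such as PKP3 with 7.54 and 14.7. With p adjusted over the list alone, DSG3, a desmosomal cadherin, and PERP were higher and DSG1 was lower; DSG3 had 148 and 263 reads (adjusted p = 0.251 in the authors' deposited table). Of 18 adherens junction genes 1 was called: CDH5, the cadherin best known from endothelium, fell from 2124 to 754 reads (log2 fold change of -1.49, adjusted p = 0.00133). CDH1, E-cadherin, had 9977 and 13590 reads (adjusted p = 0.916). That list's median was 0.02 (percentile 75.95), and 0.13 (percentile 39.5) in transcript records alone, and that of tight junctions was -0.11 (percentile 23.5) with none of 17 called and 1 with a record at an unadjusted p under 0.05. Among hemidesmosome, integrin and laminin genes 2 of 24 rose, LAMC1 among them (1.83-fold, 5376 to 9828 reads), 7 genes rose over the list alone, LAMA3 and ITGA2 among them, and the list test gave an adjusted p of 0.167. Its median of 0.22 lay at percentile 99.95, but in transcript records alone it was 0.11, at percentile 36.0.

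Of 32 listed corneal epithelial and keratinocyte markers 1 was called: KRT6A, a keratin of activated keratinocytes with close paralogs, rose 7.87-fold in the authors' deposited table, and its re-derived reads were 5, 12 and 9 in control and 71, 84 and 79 after doxycycline. Over the list alone TGM1, a crosslinking enzyme of the cornified envelope (110 and 47.7 reads), and LCN2 (838 and 390.5 reads) were lower. Fry in either direction gave the list an adjusted p of 0.001005 on re-derived reads. The median was 0.14 (percentile 98.09), and 0.35 (percentile 96.0) in transcript records alone. CDH5 also stands on the endothelial list (median -0.92 over 4 genes, percentile 0.05; -1.49 over the 3 with transcript records, percentile 0.685). None of the stromal fibroblast, immune or melanocyte and nerve markers was called, with 1, 0 and 1 gene with a record at an unadjusted p under 0.05. Their medians were -0.47, -0.26 and -0.22, all within the middle 95% of random lists, and the COL1A1 gene region had 28.9 and 16.4 reads.

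Genes of the splicing lists were not among the calls, and with 1.09% of all genes in the pool called, few would be expected. Of 14 PNN partners in the speckle and the exon junction, 17 exon junction core and decay factors, 13 SR proteins, 23 hnRNP proteins, 33 core spliceosome genes and 15 epithelial or mesenchymal splicing regulators, 0 passed the adjusted p of 0.05, and none did with p adjusted over the list alone. In the same order of lists, 1, 4, 2, 2, 4 and 1 genes had a record at an unadjusted p under 0.05. The medians were 0.03, -0.00, 0.09, 0.06, 0.12 and 0.13, at percentiles between 28.5 and 79.4. In transcript records alone they were 0.03, 0.24, 0.15, 0.23, 0.14 and 0.22, at percentiles between 20.8 and 80.9, with another sign for the exon junction and decay factors. On re-derived reads fry, testing for change in either direction, gave an adjusted p of 0.00843 for the exon junction and decay factors (10 genes) and passed none of the other 5 lists. In 1 direction fry gave SR proteins (9 genes, median 0.04) the smallest unadjusted p of the 28 lists, 0.00366 (adjusted p = 0.0695). Camera did not call SR proteins (adjusted p = 0.264 with a correlation of 0.01 and 0.518 with an estimated correlation). The smallest adjusted p among the partners was that of RNPS1, a component of the same complex as PNN, in 1 predicted variant (14.1 and 41.0 reads, adjusted p = 0.142 in the authors' deposited table). Decay-sensitive transcripts and snoRNA host genes had a median of 0.21 (percentile 83.8) with 0 of 20 called, 2 with a record at an unadjusted p under 0.05 and 1, UPP1, higher over the list alone. Proliferation genes (median 0.12, percentile 74.7), p53 targets (-0.11, percentile 20.9) and apoptosis regulators (0.01, percentile 48.8) had 0 calls, with 2, 6 and 2 genes with a record at an unadjusted p under 0.05. In transcript records alone the medians of p53 targets and apoptosis regulators were 0.13 (percentile 53.8) and 0.15 (percentile 55.3), a change of sign for p53 targets. Fry in either direction gave adjusted p of 0.00843 for p53 targets, 0.548 for proliferation and 0.181 for apoptosis regulators. Over the list alone PLK3 and TNFRSF10A were higher.

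The table holds transcript variants and no exons, so splicing could be read only as unequal change of the variants of a gene. In the re-derived reads 2 of 1393 genes passed an adjusted p of 0.05 in limma's diffSplice F test, and 103 had an unadjusted p under 0.05. EGLN1, an oxygen-sensing prolyl hydroxylase, had 25.4 and 180 reads in predicted variant X2, with 32, 18 and 23 reads in the control libraries and 244, 202 and 145 in the doxycycline libraries, whereas its curated mRNA had 20.9 and 20.4 (gene adjusted p = 0.0148). MTHFD2L, a folate enzyme, had 5.23 and 34.7 reads in predicted variant X2 and 21.6 and 16.5 in predicted variant X1 (gene adjusted p = 0.0148). Neither gene passed in 4 of the 6 fits with a library left out. SREK1 and MCFD2, each with a gene adjusted p of 0.148, RAB4A, ASCC1, NT5C3A, IL1RN, SLC38A9 and XPA followed and did not pass. ASCC1 transcript variant 4 was itself called in the authors' deposited table (2.67 to 20.7 reads). Among variants too abundant for that test, RPS24 variants a and f fell from 2761 to 1439 and from 1756 to 885 reads, while its variant c had 5249 and 5525 and its gene region 3498 and 3427, levels that are uncertain because ribosomal protein genes have many pseudogenes. ANXA2, chosen after its values were seen, rose in variant 2 from 495 to 1131 reads and had 223 and 175 in variant 3. These last differences were not tested, because the authors' deposited table tests each record on its own.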

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

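All tests in this part were chosen after the results were seen, except the comparison with cells that have no shRNA. Genomic scaffold records enter none of the comparisons over genes, and 10 of them rose in the authors' deposited table, above their level in control, while 4 fell. The folds were 23.0 for NW_001839277.1, 11.7 for NW_001841621.1 and 5.27 for NW_001841787.1, which the row descriptions leave unplaced, 5.97 for NW_001839193.2, 5.29 for NW_001839192.1, 4.75 for NW_001839215.1, 4.41 for NW_001839214.1, 4.35 for NW_001839190.2 and 4.11 for NW_001839191.2, described as chromosome 9, and 3.38 for NT_187545.1, described as chromosome 4. The 35 chromosome 9 scaffolds with a mean over 50 had a median log2 fold change of -0.23. In re-derived reads, doxycycline library a held 41.3 to 48.8% of the doxycycline reads of the 6 solved scaffolds and EGLN1 variant X2, against a median of 31.9% and a range of 21.3 to 46.6%, which overlaps, over the 38 other solved records that rose. These reads were not divided by the size factors. Library a had the largest size factor (1.21 against 1.04 and 1.01) and the most solved reads (917843 against 775253 and 767982). A record spread evenly after scaling would thus also hold more reads in library a than in b or c.

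Transcript records were higher and genomic records lower after doxycycline. A factor per library leaves the distance between the classes nearly as it is but sets the level of each: in re-derived reads of 2831 transcript and 1459 genomic records with a mean over 50, the medians were 0.09 and -0.21 with the authors' size factors and 0.28 and -0.0181 (bootstrap SE over records 0.00882 and 0.00899) without them. A fall of genomic records and a rise of transcript records therefore cannot be told apart, because the total depth of the libraries is unknown. Fewer reads from DNA or unspliced RNA in the doxycycline libraries is a candidate explanation. It needs lower values in gene regions without any listed transcript than in regions of genes with over 1000 transcript reads. The medians were -0.21 and -0.10, which differed by -0.10 (bootstrap SE over genes 0.0193, which leaves out the spread between libraries). Gene regions also hold exons, so a rise of mRNA alone would give the same order, and this difference cannot decide between them. Whether the treatment sets the genomic share stays open. That share of solved reads was 39.3, 35.0 and 32.9% in the control libraries and 35.0, 29.5 and 29.9% in the doxycycline libraries (exact two-sided permutation p = 0.3, with 0.1 the smallest that 3 against 3 can give).

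Cholesterol synthesis genes had a lower median, with 3 of 23 listed genes called, only on gene-region records, and none of 20 with transcript records alone. On re-derived reads neither camera with an estimated correlation (adjusted p = 0.518) nor fry in 1 direction (adjusted p = 0.0695) called the list. The lower level of genomic records cannot account for the whole of the lower median, because transcript records alone had a median of -0.57, below all matched random lists. Doxycycline itself and the knockdown cannot be told apart, since 0 samples in the labels lack the shRNA.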

How the results depend on the processing

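The settings on transcript records, the mean of 50, adjustment over listed records, Simes p per gene and class scaling were chosen after seeing the data. So were the re-derivation of reads, camera and fry on those reads, and the alternative settings for the gene lists, whose members were fixed beforehand. The other thresholds, pseudocounts, filters and left-out libraries were fixed before the data were examined. PNN kept its direction and its side of the threshold in 3 of 3 alternatives (log2 fold change from -1.29 to -1.14). All of these reuse its deposited fold change and p-value, re-adjusted over fewer records or set against the class median. They could hardly have changed the result and are no independent check. The count of 155 called records became 94 at an adjusted p under 0.01 and 322 under 0.2, and the 137 genes became 83 and 290, by the construction of a threshold; 249 records passed when adjusted over records with a mean of 50 or more, where fewer are tested. Their other counts stayed within 1.5 times, and between 3 and 6 gene lists passed against 4, cholesterol synthesis not among them with transcript records alone or at an adjusted p under 0.01, except that 0 passed camera with an estimated correlation (1 at an unadjusted p under 0.05) and 0 passed fry in 1 direction (6 unadjusted). The limma count of 71 records on re-derived reads became 179 with no filter and 0 without trend and robust (1228 at an unadjusted p under 0.05), and ranged from 24 to 333 with a library left out: 41 without control library a, 333 without b, 47 without c, 73 without doxycycline library a, 24 without b and 34 without c. The 2 genes with unequal variants became 0 with no filter (249 at an unadjusted p under 0.05), 1 with a minimum mean of 20, and 0 to 2 with a library left out, 0 without control library a or any 1 of the doxycycline libraries. For these the cause was not tested. With transcript records alone, medians of the hemidesmosome, epithelial-mesenchymal transition and keratinocyte lists moved inside the middle 95% of random lists and that of desmosomes moved above it.

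Of the 10 splits of the 6 libraries into 3 and 3, which are too few for a share under 0.05, the real one gave 71 records and the highest other 161, so 2 splits gave as many; that other split sets control libraries a and c with doxycycline library a against the rest, which points to a structure of the libraries beside the treatment. For unequal variants the real split gave 2 genes and the highest other 1, so 1 split gave as many. No paired analysis was possible, because the re-derived libraries a to c could not be matched to the replicate numbers of the header. A replicate block, a merge of samples 1 and 2, leaving out libraries from the authors' own calls, count tests and medians over the records of a gene were not run. Depth limits the low records: SERPINB2 rests on 2 control reads and UNC5C on 1.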

Other observations

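Further genes outside the fixed lists passed the adjusted p of 0.05 in the authors' deposited table; all those named here were chosen after their values were seen, and no test was run on them as groups. GARS, glycyl-tRNA synthetase, rose from 2391 to 4695 reads and AARS, alanyl-tRNA synthetase, from 2790 to 4931, each in a predicted transcript variant. XPOT, the tRNA exporter, rose from 3618 to 7140. CEACAM6, an adhesion molecule, rose 4.34-fold, HAS2, a hyaluronan synthase, 2.88-fold, the hyaluronan receptor CD44 1.83-fold in its gene region, FERMT1, which activates integrins, 2.62-fold, EFNB2, an ephrin ligand, 2.09-fold, and the proteases ADAM19 and ADAMTS6 2.76-fold and 2.17-fold. NQO1, a quinone reductase, rose 2.51-fold, STC1, a relative of STC2, 2.16-fold, and ST14, the epithelial protease matriptase, 1.75-fold.

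Among the genes that fell, SAT1, which acetylates polyamines, went from 1595 to 930.0 reads in its variant 1 while its gene region had 15662 and 18926, FAT3, an atypical cadherin, from 716 to 355, FREM2, a matrix protein, from 279 to 132.0 in its gene region, SLC1A3, a glutamate transporter, from 3057 to 1484 in its gene region, STEAP4, a metalloreductase, from 5722 to 3096 in its gene region, and RARRES3, a retinoid-responsive gene, from 568 to 270.4. Gene regions described as WIPF1, P3H2, BICC1 and ATP6V1B1 fell, and that described as EGFR rose, while the symbol column names another gene for each.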
